A study of Spirodela polyrhiza with 13 samples.

How the data were processed

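The series profiled messenger RNA of frond tissue of Spirodela polyrhiza, the greater duckweed, a small floating aquatic plant whose leaf-like body is called a frond. The 13 libraries of wild-type plants covered developmental stages 2 to 6, with 3 libraries each at stages 2, 3 and 4 and 2 libraries each at stages 5 and 6. Per the labels' protocols, plants grew in SH medium renewed every 7 days, under 16 h of light and 8 h of darkness, at 23 °C by day and 20 °C by night, and libraries came from a stranded messenger RNA kit. The labels do not say whether the libraries of a stage came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical.

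The authors deposited 1 table of FPKM values (fragments on a gene, divided by its length in kilobases and by the library total) for 19623 gene IDs, 1 column per library, and each column name equalled the title of 1 sample. Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic 0.39, HISAT2 2.2.1, Picard 2.25.5 and HTSeq 0.11.3 were used. The genome build, the gene annotation, the strand setting of the counting and any further scaling between libraries are not given in the sources used here. A stranded kit counted without strand cannot part a gene from an overlapping antisense gene, and reads of near-identical copies can be split or dropped by a counter, so single genes carry that uncertainty. Values in FPKM are relative to the library total, so a gain of some genes lowers the others.

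The table pairs no gene ID with a name, and no annotation was used here. Before the data were examined, 27 lists of hormone, cell wall, cell death, photosynthesis and cell type marker genes had been fixed by product name. None could be applied to bare IDs, and the planned tests of these lists were not run. Genes are therefore given by ID. The rule for naming them, fixed before the data were examined, took for each pair of stages the 2 genes with the largest rise and the 2 with the largest fall in log2(FPKM + 1) among those with adjusted p under 0.05, a mean of at least 1 FPKM at the higher stage and no overlap between the libraries of both stages. No ID was translated into a gene name, a chromosome or a position.

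The depth behind the FPKM values could be read from the values themselves. Within a gene, FPKM values are whole multiples of what 1 read is worth, and the ratio of these steps between libraries gave the relative library totals. With these, the values of 100% of the 17445 genes with any value came out as whole reads within 0.001 reads. Library totals came out whole (largest distance 2.6e-05), from 7708200 to 10910370 reads assigned to genes, and the recovered reads summed to at least 99.995% of them. Among 9766 genes with over 2000 reads, 100% of the lengths implied by the values were multiples of 3, as for models of coding sequence without untranslated regions, and they are called coding lengths. On simulated reads of 17295 genes, the same steps returned all reads for 99.9% of genes and all 13 library totals. Recovered reads served for depth, for counting intervals and for an added alternative test, not for the main test.

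The main test was limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) for the 15608 genes with at least 1 FPKM in at least 2 libraries. All 13 libraries entered 1 fit with a mean per stage and 8 residual degrees of freedom, with a mean-variance trend, so that stages with 2 libraries shared the spread estimated over all stages. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and genes with adjusted p under 0.05 were called. Consecutive stages were compared, then stage 2 with stage 6, and an F test asked for any difference among the 5 stages. A change on the log2(FPKM + 1) scale understates the change of genes near 1 FPKM. Counts of genes changed at least 2-fold or 4-fold use this scale. Falls of named genes given in folds are ratios of mean FPKM, which can be larger. The p-values belong to the log2 changes. Levels are means of FPKM ± SD over the libraries of a stage. In simulated reads for the real genes, with 100 genes changed 2-fold and 100 changed 1.5-fold, the test called 87% of the 2-fold and 56% of the 1.5-fold changes from stage 2 to stage 3, over 15548 genes. It called 88% and 38% from stage 3 to stage 4 over 15548 genes, 80% and 26% from stage 4 to stage 5 over 15553 genes, and 72% and 13% from stage 5 to stage 6 over 15572 genes. Each comparison was simulated once, with its own random genes and the same spread at every stage. Differences between comparisons with equal numbers of libraries can therefore come from the draw alone. The changed genes were drawn only from those with a mean of at least 2 FPKM, so the shares do not cover rarer genes. Fewer genes were changed than the data called, so these shares do not give the power of the real comparisons. Counts of called genes were not tested against each other.

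Alternatives fixed before the data were examined were other pseudocounts, other filters, rescaling to equal totals, median ratio scaling, quantile normalization, the replicate number as a block, other variance priors, library weights, fits of 2 stages alone, a 2-fold minimum, and leaving out each library. Added after seeing the data were limma's voom model on the recovered reads, the same on reads thinned to the lowest total, and a fit of stages 2 to 4 alone. Within every stage, replicate libraries differed by more than sampling noise, with a mean chi-square per gene between 6.93 and 17.9, so none was counted as a repeat of another. Calculations outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The labels name no sequencing batch.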

Results

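Gene expression was measured by RNA sequencing in frond tissue of the greater duckweed Spirodela polyrhiza at 5 developmental stages, numbered 2 to 6. The study was concerned with plant hormones and with aerenchyma, the gas-filled tissue that forms inside the frond as it develops. Libraries held a mean of 9819520 reads on genes at stage 2 (SD 1005798, n = 3), 9223080 at stage 3 (SD 87350, n = 3), 9782039 at stage 4 (SD 754888, n = 3), 8241018 at stage 5 (SD 753519, n = 2) and 8304332 at stage 6 (SD 820268, n = 2), as recovered from the FPKM values. Of 19623 gene IDs, 2178 had no read in any library, and 15608 reached at least 1 FPKM in at least 2 libraries and were tested. Genes above 1 FPKM numbered 14644 ± 46.6 (SD, n = 3) at stage 2 and 15063.5 ± 117 (SD, n = 2) at stage 6.

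Libraries of the same stage resembled each other more than libraries of the first and last stages. Within stages, the correlation of log2(FPKM + 1) across genes lay between 0.978 and 0.990 for all pairs of libraries. Between stages 2 and 3 it averaged 0.973 over 9 pairs, between stages 3 and 4 it averaged 0.976 over 9 pairs, and between stages 5 and 6 it averaged 0.968 over 4 pairs. Single pairs reached 0.985 between stages 2 and 3 and 0.983 between stages 3 and 4. These lay above the lowest pairs within stage 3 (0.978) and within stage 4 (0.980). The step from stage 4 to stage 5 had the lowest mean correlation of the 4 consecutive steps, 0.929 over 6 pairs, and stages 2 and 6 had a mean of 0.817 over 6 pairs. The first principal component held 69.7% of the variance between libraries.

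**Figure D1:**
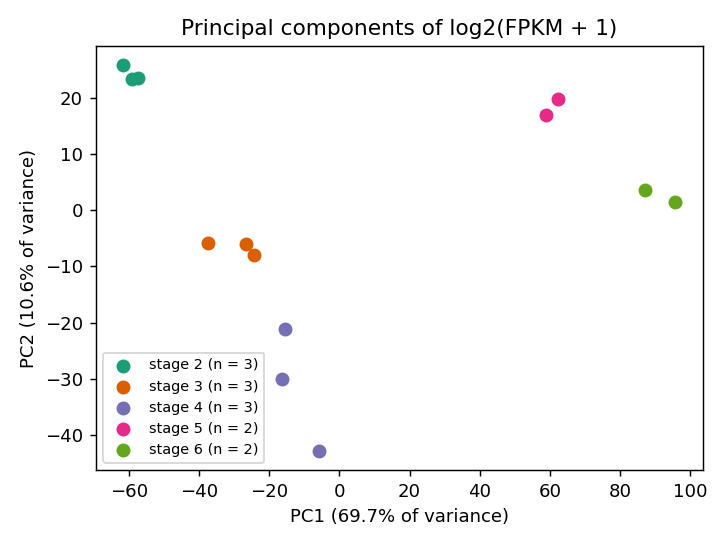
Each point is 1 of the 13 libraries, placed by the first (x axis, 69.7% of variance) and second (y axis, 10.6%) principal components of log2(FPKM + 1) over the 15608 tested genes and coloured by stage. Stages 2, 3 and 4 lie on one side of the first component and stages 5 and 6 on the other.

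The comparison of all stages asked which genes differed in level at any point of frond development. The F test of limma called 12372 of 15608 genes (79.3%) at adjusted p under 0.05. Of the called genes, 5170 (41.8%) had their highest mean at stage 2 and 3165 (25.6%) at stage 6, while 1622, 1352 and 1063 had it at stages 3, 4 and 5. Means were higher at each successive stage for 1317 called genes (10.6%) and lower at each successive stage for 3157 (25.5%). Stages ranked at random would give 0.833% for either order. Called genes were picked for differing between stages, and 1 large step alone makes such orders more frequent. The gap to a random order therefore does not show stepwise change. For 6711 called genes the largest of the 4 steps lay between stages 4 and 5, against 1840, 962 and 2859 for the steps from stages 2, 3 and 5. With median ratio scaling the order of the end stages turned, with 4171 genes highest at stage 2 and 4416 at stage 6. Under that scaling the genes higher at each stage numbered 2028 and those lower at each stage 1914, and 758 genes had their highest mean at stage 3.

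Reads were spread less evenly over genes at the later stages. The 100 genes with most reads held 11.6% ± 0.127 (SD, n = 3) of the reads at stage 2, 11.5% ± 0.361 (n = 3) at stage 3, 12.6% ± 0.675 (n = 3) at stage 4, 16.0% ± 0.289 (n = 2) at stage 5 and 18.5% ± 0.851 (n = 2) at stage 6. Median FPKM over all listed genes was 16.3 ± 0.306 (SD, n = 3) at stage 2 and 14.1 ± 0.509 (n = 2) at stage 6. For both measures the libraries of stages 2 and 6 did not overlap, and the exact two-sided permutation test gave p = 0.2, the smallest that 3 against 2 libraries allow. The gene with the highest FPKM was Spipo23G0000600 (coding length 159 bases) in 7 libraries and Spipo14G0042700 (537 bases) in 6, both named here after their values were seen. Spipo23G0000600 was at 11575 ± 731 FPKM (SD, n = 3) at stage 4 and 19468.5 ± 2587 (n = 2) at stage 5, a log2 change of 0.75 (SE 0.17, adjusted p = 0.00394, limma). Spipo14G0042700 rose from 8730 ± 594 FPKM (n = 3) at stage 2 to 18234 ± 1020 (n = 2) at stage 6 (adjusted p = 7.42e-06, limma). Its log2 change of 0.19 from stage 4 to stage 5 was not called (SE 0.13, adjusted p = 0.238, limma). Scaling each library by its median ratio moved the median change of all tested genes up by 0.18 (log2) from stage 4 to stage 5 and by 0.30 from stage 2 to stage 6, and by less than 0.1 in the other steps. Total counts of rises and falls between stages are therefore given under both scalings, and other counts are as deposited unless stated.

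**Figure D2:**
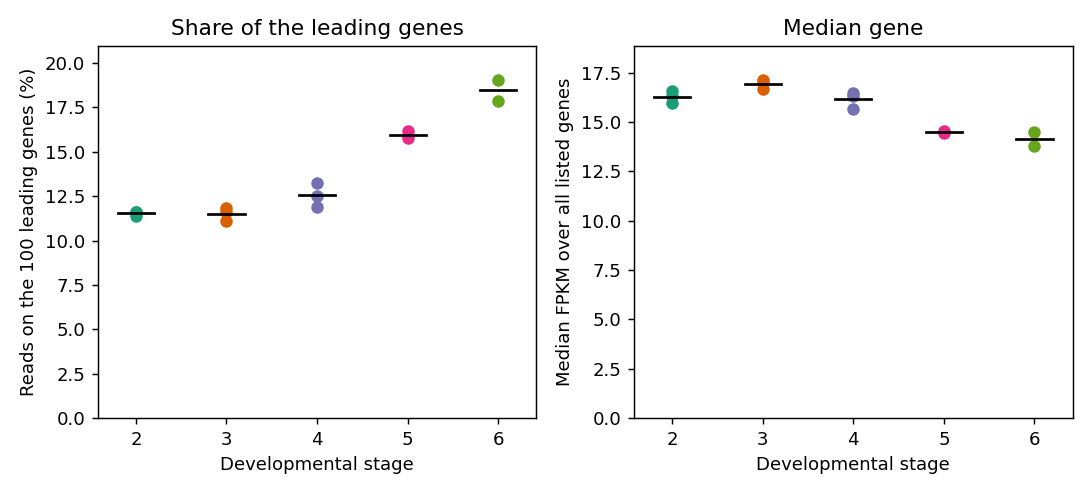
Points are single libraries and bars the means of a stage, with 3 libraries at stages 2 to 4 and 2 at stages 5 and 6; the x axis is the developmental stage. The left panel shows the percent of reads on the 100 leading genes of each library, 11.6% at stage 2 and 18.5% at stage 6 on average, and the right panel the median FPKM over all listed genes, 16.3 and 14.1.

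From stage 2 to stage 3, 2411 genes (15.4% of those tested) were called, of which 1375 rose and 1036 fell. Large changes on the log2(FPKM + 1) scale were mostly rises, with 260 genes that rose and 26 that fell at least 2-fold. On that scale 29 rose and none fell at least 4-fold, out of the same 2411 called genes. Spipo22G0026000 (378 bases) rose from 0.850 ± 0.620 FPKM to 17.0 ± 7.57 (SD, n = 3 each), a log2 change of 3.26 (SE 0.28, adjusted p = 5.84e-05, limma) resting on 9 and 178 reads. Spipo1G0112500 (393 bases) rose from 4.03 ± 2.72 to 39.0 ± 7.73 FPKM, a log2 change of 3.14 (SE 0.34, adjusted p = 0.00033, limma). Its mean was higher at each later stage, reaching 166 ± 17.5 FPKM (n = 2) at stage 6. Spipo20G0023600 (630 bases) fell 4.71-fold, from 32.5 ± 15.7 to 6.89 ± 1.44 FPKM (log2 change -1.97, adjusted p = 0.00377, limma). It was between 4.68 and 6.67 FPKM on average at the later stages. Spipo1G0048900 (450 bases) fell 3.63-fold, from 34.6 ± 7.47 to 9.56 ± 3.26 FPKM (log2 change -1.78, adjusted p = 0.00172, limma). The number of called genes depended on single libraries: it was 1601, 1275 and 759 without stage 2 replicates 1, 2 and 3, and 811 and 1016 without stage 3 replicates 2 and 3. It was 4972 with library weights, and with median ratio scaling 1255 genes rose and 1131 fell. Quantile normalization gave 1196 rises and 1206 falls, and leaving out stage 2 replicate 3 gave 568 and 191.

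From stage 3 to stage 4, 469 genes (3.00%) were called, of which 298 rose and 171 fell. At least 2-fold changes were seen for 135 genes that rose and 35 that fell. Spipo1G0120500 (483 bases) rose from 6.89 ± 2.32 to 111 ± 77.4 FPKM (SD, n = 3 each), a log2 change of 3.67 (SE 0.38, adjusted p = 0.000631, limma). Spipo1G0121700 (276 bases) rose from 8.80 ± 4.11 to 73.6 ± 30.4 FPKM, a log2 change of 2.92 (SE 0.40, adjusted p = 0.00343, limma). Both named genes that fell had their lowest mean of the series at stage 4. Spipo3G0081000 (171 bases) fell 5.94-fold, from 71.9 ± 23.2 to 12.1 ± 4.31 FPKM (log2 change -2.48, adjusted p = 0.00343, limma). It was at 33.3 ± 0.969 FPKM (n = 2) at stage 5. Spipo4G0013100 (1533 bases) fell 4.71-fold, from 55.3 ± 22.8 to 11.7 ± 5.56 FPKM (log2 change -2.13, adjusted p = 0.00987, limma). It was at 76.1 ± 22.7 FPKM (n = 2) at stage 5. Its adjusted p (limma) was 0.0506 without stage 4 replicate 3 and 0.0574 in a fit of stages 3 and 4 alone. The number of called genes was 160 and 186 without stage 3 replicates 2 and 3, 186 and 129 without stage 4 replicates 2 and 3, 146 in a fit of these stages alone and 3402 with library weights. With median ratio scaling 80.0% of 500 called genes rose, against 63.5% as deposited. Library weights turned the balance, to 39.5% rises. Without stage 3 replicates 2 and 3 the falls numbered 19 and 21.

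From stage 4 to stage 5, 7119 genes (45.6%) were called, the most of the 4 steps although fewer libraries were compared than in the earlier steps. As deposited, 2331 genes rose and 4788 fell, so that 32.7% of calls were rises. With median ratio scaling 3369 rose and 2874 fell, 54.0% rises. No gene called under both scalings changed sign, though 1 factor per library could hardly turn a called change. Changes of at least 4-fold were mostly rises, with 287 genes against 33 that fell, or 342 against 24 with median ratio scaling. At least 2-fold, 948 rose and 808 fell as deposited, and 1248 and 435 with that scaling. A pair of genes near the detection limit at stages 2 to 4 were abundant at stage 5. Spipo0G0190900 (672 bases) rose from 0.484 ± 0.489 FPKM (n = 3) to 92.9 ± 19.7 (n = 2), a log2 change of 6.02 (SE 0.27, adjusted p = 1.8e-08, limma) from 10 to 1039 reads. Spipo9G0025900 (417 bases) rose from 0.481 ± 0.210 to 79.2 ± 18.7 FPKM, a log2 change of 5.75 (SE 0.22, adjusted p = 1.23e-08, limma) from 6 to 550 reads. Spipo2G0070100 (2283 bases) fell 13.7-fold, from 507 ± 239 to 37.1 ± 6.31 FPKM (log2 change -3.63, adjusted p = 3.59e-06, limma). Its means were 346 and 396 FPKM at stages 2 and 3. Spipo9G0028100 (324 bases) fell 12.9-fold, from 30.7 ± 14.9 to 2.38 ± 1.11 FPKM (log2 change -3.14, adjusted p = 0.000129, limma). Stage 4 was its only stage with a mean above 5 FPKM. With a pseudocount of 0.01 the log2 change of Spipo0G0190900 was 9.09.

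**Figure D3:**
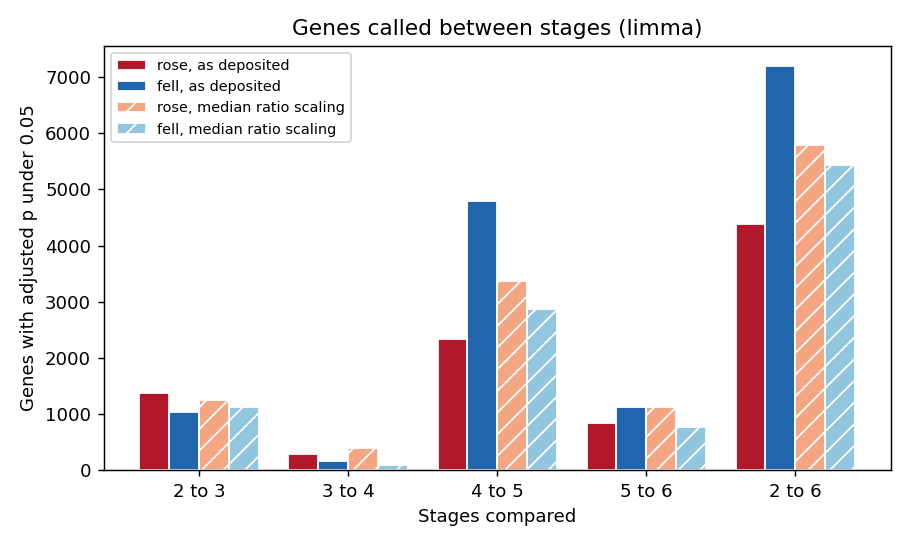
Bars show the number of genes with adjusted p under 0.05 (y axis) that rose or fell between the stages compared (x axis), from FPKM as deposited (solid) and with median ratio scaling (hatched). From stage 4 to stage 5, 4788 genes fell as deposited and 2874 with median ratio scaling.

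From stage 5 to stage 6, 1959 genes (12.6% of those tested) were called, of which 835 rose and 1124 fell as deposited. With median ratio scaling 1130 rose and 772 fell, 59.4% rises against 42.6%. At least 2-fold changes were again mostly rises, with 318 genes against 65, or 434 against 46 with median ratio scaling. Spipo30G0000700 (570 bases) rose from 1.47 ± 0.468 to 38.7 ± 8.43 FPKM (SD, n = 2 each), a log2 change of 4.00 (SE 0.41, adjusted p = 0.00118, limma), after means below 1 FPKM at stages 2 to 4; its adjusted p was 0.183 with a pseudocount of 0.01. Spipo2G0110300 (492 bases) had 1 read over both stage 5 libraries and 84 over both stage 6 libraries, a ratio of 83.4 with a 95% exact interval of 14.6 to 3331 for counting error alone. Its log2 change was 3.34 (SE 0.43, adjusted p = 0.00336, limma), or 5.83 with a pseudocount of 0.1, and its mean at stage 4 was 6.08 ± 2.80 FPKM (n = 3). Spipo6G0039300 (567 bases) fell 4.59-fold, from 6.99 ± 1.48 to 1.52 ± 0.751 FPKM (log2 change -1.68, adjusted p = 0.00426, limma). Its mean was lower at each stage from 15.5 FPKM at stage 2. Spipo21G0015100 (315 bases) fell 3.50-fold, from 6.35 ± 0.237 to 1.81 ± 1.98 FPKM (adjusted p = 0.0149, limma). That call rested on single libraries, with a log2 change of -0.80 and an adjusted p of 0.0579 without stage 6 replicate 1, against -1.59 with all libraries. The number of called genes was 571 and 616 without stage 5 replicates 1 and 2, 304 without stage 6 replicate 1 and 778 in a fit of these stages alone. The balance turned without stage 6 replicate 1, to 181 rises and 123 falls, and was 311 and 305 without stage 5 replicate 2.

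Between the first and the last stage, 11582 genes (74.2%) were called, of which 4387 rose and 7195 fell as deposited and 5783 rose and 5440 fell with median ratio scaling. Changes of at least 4-fold were mostly rises under both scalings, with 1010 genes that rose and 215 that fell as deposited and 1345 and 65 with median ratio scaling. At least 2-fold, 2635 rose and 3577 fell as deposited, while 3414 rose and 2033 fell with median ratio scaling. Spipo1G0108500 (924 bases) rose from 1.36 ± 1.23 FPKM (n = 3) to 309 ± 147 (n = 2), a log2 change of 7.09 (SE 0.38, adjusted p = 1.74e-08, limma), with means of 8.42, 64.6 and 196 FPKM at stages 3, 4 and 5. Spipo19G0027700 (357 bases) rose from 36.7 ± 12.7 to 4628 ± 1187 FPKM, a log2 change of 6.98 (SE 0.33, adjusted p = 6.86e-09, limma), and most of its rise lay between 324 FPKM at stage 4 and 3695 at stage 5. Spipo7G0057500 (342 bases) fell 11.4-fold, from 480 ± 112 to 42.2 ± 24.3 FPKM (log2 change -3.57, adjusted p = 1.63e-06, limma). Spipo1G0048900, also named for its fall from stage 2 to stage 3, fell 14.7-fold, from 34.6 ± 7.47 to 2.36 ± 0.902 FPKM (log2 change -3.41, adjusted p = 4.05e-07, limma).

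**Figure D4:**
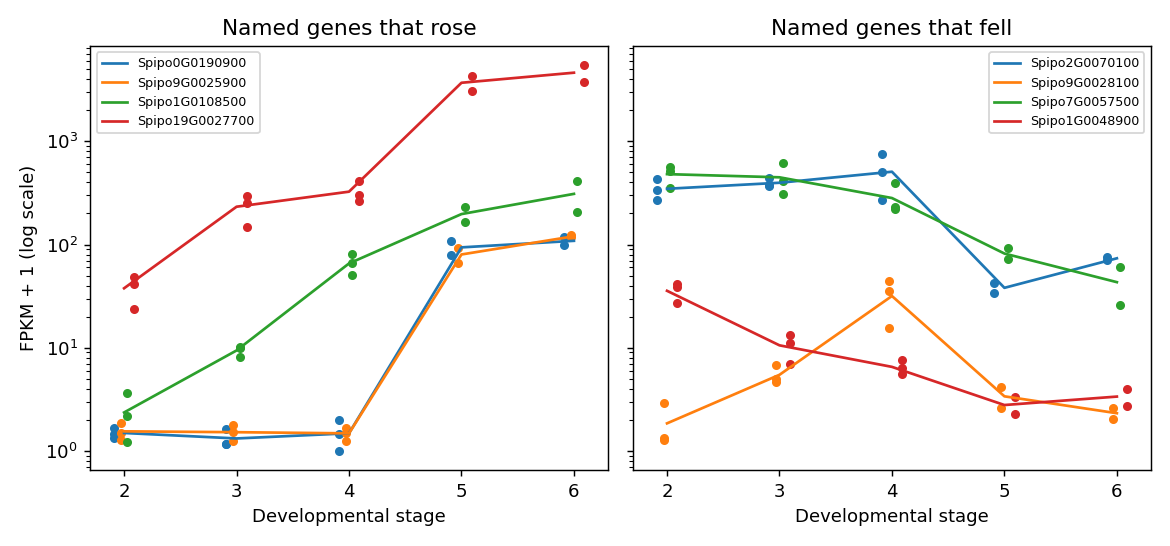
FPKM + 1 on a log axis (y) against developmental stage (x) for the genes named from stage 4 to 5 and from stage 2 to 6, those that rose on the left and those that fell on the right. Points are single libraries, shifted sideways for clarity, and lines join the stage means; Spipo0G0190900 and Spipo9G0025900 stay below 1 FPKM on average until stage 4 and reach 92.9 and 79.2 FPKM at stage 5.

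For the genes that changed at least 2-fold over the whole series, the median change was greatest between stages 4 and 5. The 2635 genes that rose had median log2 changes of 0.44, 0.18, 0.64 and 0.46 over the 4 consecutive steps, and the 3577 that fell had -0.32, -0.16, -0.55 and -0.38. The step from stage 3 to stage 4 was called in the same direction for 240 of the rising and 68 of the falling genes. The step from stage 4 to stage 5 held 39.8% of the summed change of the rising genes and 39.96% of that of the falling genes, and with median ratio scaling 41.4% of that of 3414 rising and 35.6% of that of 2033 falling genes. Among the rising genes 1436 were called as rising at that step and 83 as falling, and among the falling genes 2253 were called as falling. There were 11 genes that had no read in any stage 2 library and at least 5 FPKM in each stage 6 library. Of these, 9 first were at 1 FPKM or more in each library at stage 5 and the others at stage 4. No gene had at least 5 FPKM in each stage 2 library and no read at stage 6. With up to 3 reads allowed over the stage 2 libraries, 34 genes met the first criterion. With up to 3 reads allowed over the stage 6 libraries, 2 genes met the opposite one.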

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

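The fits of recovered reads, of thinned reads and of stages 2 to 4 alone were chosen after seeing the data; the other alternatives were planned. Counts of called genes from stage 4 to stage 5, from stage 2 to stage 6 and across all stages stayed within 1.5 times the value with all libraries under every alternative run except the 2-fold minimum and, across stages, the fit of stages 2 to 4, which called 5155 genes. With the 2-fold minimum the counts were 286, 170, 1756 and 383 for the consecutive steps, 6212 from stage 2 to stage 6 and 7149 across stages, by construction fewer. Library weights called 4972 genes from stage 2 to 3 and 3402 from stage 3 to 4, of which 39.5% rose, against 1399 from stage 5 to 6; the cause was not tested. Fits of the 2 stages alone called 146 from stage 3 to 4 and 778 from stage 5 to 6, with fewer samples behind the spread. Leaving out 1 library, which for stages 5 and 6 leaves a lone library assumed to vary like the others, gave 759 to 2712 genes from stage 2 to 3, 129 to 513 from 3 to 4, 5106 to 7165 from 4 to 5, 304 to 2338 from 5 to 6, 10274 to 11680 from 2 to 6 and 11593 to 12402 across stages. Deviations of libraries with the same replicate number had correlations from -0.24 to 0.37, with 7 of 23 above 0.1, and 8 of 13 libraries were closest on average to their own number. Among stages 2 to 4, same-number pairs correlated by 0.21 to 0.37 for replicate 1, 0.073 to 0.28 for replicate 3 and -0.085 to 0.084 for replicate 2. Pairs of replicate 1 with replicate 3 gave -0.41 to -0.15. A link between equal numbers at stages 2 to 4 therefore cannot be excluded. No label ties the numbers, so they were not taken as pairs. With a replicate block the counts were 2661, 611, 7031, 2372, 11633 and 12344, all within 1.5 times. The voom model on recovered reads called 2776, 537, 6867, 1723, 11442 and 12255 genes. The balance of rises and falls moved by over 10 percentage points with median ratio scaling in 4 comparisons, and with quantile normalization from 63.5% to 73.8% rises from stage 3 to 4. Fits of 2 stages alone gave 79.5% rises from stage 3 to 4 and 62.3% from stage 5 to 6. Of 548 alternative values of the 20 named changes, 541 stayed called with the same sign, 7 lost the call and none reversed. These changes were picked as the largest called, and leaving out a library of another stage cannot move their size. The count therefore says little about stability. Camera and fry tests of gene lists were not run because no ID could be tied to a name. Depth limits genes near 1 FPKM, where a few reads carry a value.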

Other observations

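The test of scaling, and the descriptions by abundance, coding length and overlap between steps, were chosen after their results were seen in part. Among 9518 genes with a mean between 10 and 100 FPKM over all libraries, 25.04% rose and 50.4% fell from stage 2 to stage 6 as deposited, and 35.05% and 37.5% with median ratio scaling, so the excess of falls depends on the scaling. Of 131 genes at 1000 FPKM or more, 34.4% rose at least 2-fold as deposited and 37.4% with median ratio scaling. These shares were 15.5% and 20.7% between 100 and 1000 FPKM, and 13.2% and 18.05% between 10 and 100. They were 25.1% and 30.3% from 1 to 10 FPKM, and 31.2% and 36.4% below 1. A high share was thus not particular to abundant genes. Of the 131 genes, 26.0% fell at least 2-fold as deposited and 2.29% with median ratio scaling. The classes used means that include stage 6, so a strong rise could itself move a gene into a higher class. Genes with a transient extreme were few: 54 of the genes called across stages were highest at stages 3 to 5 by at least 2-fold over both stages 2 and 6, and 51 were lowest there by as much.

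Many genes called from stage 2 to 3 were called the same way from stage 5 to 6, steps that share no library. As deposited, 252 genes rose in both, against 73.6 expected of independent lists, and 359 fell in both, against 74.6. With median ratio scaling these were 309 against 90.9 and 260 against 55.9. As deposited, 8 genes rose in the earlier and fell in the later step, against 99.0 expected. An excess of shared calls was not particular to this pair of steps. For stages 3 to 4 with 5 to 6, 77 genes rose in both, against 15.9 expected, and 28 fell in both, against 12.3. There 4 rose and then fell, against 21.5, and 16 fell and then rose, against 9.15. For stages 2 to 3 with 4 to 5, 401 rose in both, against 205, and 413 fell in both, against 318. There 241 rose and then fell, against 422, and 39 fell and then rose, against 155. The expected numbers assume independent lists, whereas all steps used the same fit and the same spread estimate of each gene. They are therefore a rough reference only. Across genes, which are not independent replicates, the changes from stage 2 to 3 and from 5 to 6 correlated by 0.49. Other splits of the stage 2 and 3 libraries reached 0.45 in size. The other 2 of the 3 correlations computed lay below the highest of other splits. They were 0.22 for stages 2 to 3 with 4 to 5, where other splits reached 0.30, and 0.21 for stages 3 to 4 with 5 to 6, where they reached 0.48. Each other split mixed unequal numbers of libraries of the 2 stages and so kept part of their difference. The splits therefore do not measure noise alone, and none of the 3 correlations can be judged by them.

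The share of genes that fell differed by coding length, in a direction that differed between steps. From stage 4 to stage 5, 24.3% of genes with coding lengths of 90 to 525 bases fell and 40.2% of those of 1734 bases or more, or 14.3% and 23.7% with median ratio scaling. As deposited the shares went the other way in the other steps: 7.87% and 4.55% from stage 2 to 3, 1.59% and 0.609% from stage 3 to 4, and 7.68% and 6.32% from stage 5 to 6. The shares that rose were 15.9% and 9.27% from stage 4 to 5 and 5.19% and 3.66% from stage 5 to 6. They were 6.47% and 9.36% from stage 2 to 3, and 1.94% and 1.64% from stage 3 to 4. Across genes, the rank correlation (Spearman) of coding length with change was -0.093 from stage 4 to 5 and -0.080 from 5 to 6. It was 0.0015 from stage 2 to 3 and 0.049 from stage 3 to 4. The share that fell thus does not give the direction of change by length. At equal depth, 16104 ± 46.8 genes (SD, n = 3) would have had a read at stage 2 and 16414 ± 0.903 (n = 2) at stage 6.

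More genes fell than rose from stage 4 to stage 5 as deposited. The pseudocount might hide the rises of rare genes, but 31.5% of calls were rises with a pseudocount of 0.01, close to the 32.7% with 1. Called rises numbered 2175 with 0.01 and 2331 with 1. A small pseudocount also widens the spread of genes with few reads, so this test could miss such rises and does not decide. Scaling to the library total may account for the imbalance: with median ratio scaling 54.0% of calls were rises. That scaling centres the median change near 0, so it cannot tell a general fall of most transcripts from a gain of a few. Which of these took place stays open, as does a developmental cause, which was not tested.

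The step from stage 4 to stage 5 called the most genes. The lower totals at stages 5 and 6 are argued against as the cause, since with reads thinned to 1 total this step still called 2.67 times as many genes as the next largest step. An unrecorded batch that parts stages 2 to 4 from stages 5 and 6 cannot be told apart from development, because no stage lies on both sides. If it were the whole cause, the change should be unrelated to earlier changes. Across genes the change from stage 4 to 5 correlated with that from stage 2 to 3 by 0.22, but other splits of those 6 libraries reached 0.30 in size. Those splits keep part of the difference between stages 2 and 3, so they do not measure noise alone and the test does not decide. A longer interval or a larger developmental change between stages 4 and 5 stays open, untested.

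Genes with consecutive IDs may be regulated together, if IDs follow the order of genes on the genome, which was not checked. Their changes from stage 2 to stage 6 correlated by 0.104 over 13598 pairs, above all 1000 shuffles, which reached 0.027. The correlation was 0.042 at a distance of 2 IDs and -0.0013 at 5. Pairs whose coding lengths differ by over 20% still correlated by 0.0719, with 0.027 the highest of the shuffles. Reads shared between neighbouring copies of similar length are therefore argued against as the whole cause. Copies of unequal length can share reads too, and no sequences were compared, so the length split cannot exclude shared reads in general. Pairs of similar length correlated by 0.213, so shared reads or duplicated genes as a part or the whole of it stay open.

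For the steps from stage 2 to 3 and from stage 3 to 4, 1 of the 10 splits of the 6 libraries, the real one, gave the called 2411 and 469 genes, and the highest other split gave 0 in both (limma). At an unadjusted p under 0.05 the real splits gave 5132 and 3166 genes and the highest others 1454 and 1528. With 10 splits no share under 0.05 can be had. Every other split also put libraries of both stages into each group, which widens the spread of the genes that differ between the stages. Few calls were therefore likely from the other splits in any case, and their 0 does not show what random grouping alone would give.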
